A study of Mus musculus with 12 samples.

How the data were processed

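Total RNA of 12 mouse samples was measured on 1 Affymetrix array each, from 6 ug of RNA per the labels' protocols. The deposited values are on a log2 scale, made with RMA (background correction, quantile normalization and summary of the probes of a probe set) in Partek per the submitters' processing notes. Versions are not given in the sources used here. Samples were grouped by the labels into wild type and Smad3-/- on regular or high fat diet, and obese mice given IgG or an antibody against TGF-beta, with 2 arrays (a and b) per group. The medians and SDs of the arrays differ between the diet and genotype experiment (8 arrays) and the antibody experiment (4 arrays), so the 2 may have been normalized separately, and all comparisons were made within an experiment. No detection calls were used here, and no per-sample value column was left unused.

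Probe sets were named through the platform annotation. Of 45101 probe sets, 34958 named 1 gene, 932 several and 9211 none. For each of the 18194 genes, the probe set with the highest mean over the 12 arrays was used among those naming only that gene (9012 genes had several). Symbols were looked up by gene ID in a table of the assembly GRCm38.p6, where 18032 genes matched and 0 symbols changed, and 162 kept the symbol of the annotation.

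Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit on group means over all 12 arrays, contrasts, eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 6 residual degrees of freedom and 20.4 prior ones. The 8 comparisons were diet within each genotype, genotype within each diet, their interaction, antibody against IgG, and genotype and diet averaged over the other factor. The number of arrays limits the precision, with SEs of 0.10 to 0.24 log2 for named called genes in comparisons of 2 groups and of 0.14 to 0.23 for the interaction. Genes were also compared across comparisons that share no array, by correlation of log2 differences over genes and by counts of shared calls.

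The 39 gene lists, written before the data were examined, were tested with camera (preset correlation 0.01, adjusted over lists within a comparison), and again with an estimated correlation and with fry. The median of every list is in the map of list medians. Lists of other tissues, immediate early genes, clock genes and sex-linked genes served to show differences in dissection, handling or sex, and the sex-linked list had at most 1 called gene in any comparison.

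Genes were named by a rule fixed before the data were examined. It takes Smad3, the 8 genes with the highest and the 8 with the lowest log2 difference among called genes whose arrays did not overlap between sides (overlap was not asked of the interaction), passing over RIKEN, Gm, LOC, expressed-sequence and immunoglobulin or T cell receptor segment symbols, up to 4 members of a list with the smallest unadjusted p, and preset genes such as Ucp1, Lep, Adipoq and Tgfb1. The 356 pairs of gene and comparison taken from it were all recomputed under the alternatives. The text prints part of them, and gives how many preset genes passed in each comparison.

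Alternatives were eBayes without a trend or robust, a filter on dim probe sets (under the 40th percentile), the mean of a gene's probe sets, every probe set on its own, arrays centred on their medians, quantile normalization over all 12 arrays, only the arrays of an experiment, arrayWeights, the replicate letter as a block, 2 groups of 4 arrays, a minimum of 1.5-fold, and leaving out each array in turn. In the last case the lone array of a group was taken to vary like the other groups. Fits without the KO_RD or the WT_RD group were added after seeing the data.

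The fit was tested on simulated data with the real genes' levels and spreads over 18194 genes. For the comparisons of 2 groups, changes of 1 log2 were called in the right direction for 94% of genes for diet in wild type, 100% for diet in the knockout, 94% and 97% for genotype on regular and high fat diet and 91% for the antibody, and for 67.2% for the interaction. Changes of 0.5 log2 were called for 31.3% (antibody) to 41.8% (genotype on regular diet), and for 2.99% for the interaction. Each simulation changed only 66 or 67 genes per size and 1 gene list, whereas 1922 to 4423 genes were called in the data. The adjustment over genes therefore acts differently there, and these rates do not give the sensitivity of the reported comparisons. Of 17917 unchanged genes, between 1 and 15 were called.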

Results

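Gene expression was measured on 12 single-sample arrays of total RNA from mice, 2 arrays (a and b) in each of 6 groups. Wild-type C57BL/6 mice were on a regular diet or on a high fat diet with 55% fat. Mice labelled Smad3-/-, on a mixed background of C57BL/6 and NIH Black Swiss, were on the same 2 diets. Smad3 carries TGF-beta signals from the receptor to the nucleus. In a separate experiment, mice already obese from the diet received control IgG (clone 13C4) or an antibody against TGF-beta (clone 1D11) by injection into the peritoneum 3 times a week for 8 weeks. The series title poses the question of whether blocking this pathway protects against obesity and diabetes. Genotype within each diet asks what loss of Smad3 changes without and with the diet, the antibody what blocking TGF-beta changes once mice are obese, diet within genotype how each genotype responds to fat, and the interaction whether these responses differ. The labels give no tissue. Adipoq, which encodes the fat-cell hormone adiponectin, averaged between 13.07 and 14.15 log2 units in the 6 groups, against array medians from 6.03 to 6.39.

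The 45101 probe sets gave 1 value for each of 18194 genes. The 8 diet and genotype arrays had medians of 6.32 to 6.39 and SDs over probe sets of 1.64 to 1.74. The 4 antibody arrays had medians of 6.03 to 6.04 and SDs of 2.15 to 2.17, so levels are not compared between the 2 experiments and each difference below lies within one. Arrays of a group correlated at r = 0.992 to 0.996 over genes. Their differences had an SD of 0.182 to 0.214 log2. The number of arrays limits the precision, and the labels do not say that a and b came from separate animals, so p-values measure only the spread between these arrays, which may be technical. Values near an array's median may be background, and folds from such values may be compressed. Each log2 difference is given with its SE or within a stated SE range, from 2 arrays a side, or 4 a side where averaged over diets or genotypes. The Gapdh probe sets for the 3' and 5' ends, whose difference grows as RNA degrades, differed by 0.12 and 0.14 log2 on the WT_RD arrays and by 0.28 to 0.50 on the other arrays of that experiment, and those of actin by 0.77 to 0.80 and 0.90 to 1.12. Where a gene list has only 1 p, from limma's camera test, its call also held with an estimated correlation.

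No Smad3 probe set was called different between arrays labelled Smad3-/- and wild type. The brightest averaged 8.90 ± 0.05 (SD, n = 2) and 8.92 ± 0.05 in wild type on regular and high fat diet, and 9.13 ± 0.05 and 9.09 ± 0.08 on the arrays labelled Smad3-/-. Averaged over diets the difference was 0.20 ± 0.07 (SE, limma adjusted p = 0.0575). The other probe sets differed by 0.18 ± 0.11 and -0.06 ± 0.12. Quantile normalization applied again put the first difference at 0.34 (limma adjusted p = 0.000999), higher on the arrays labelled Smad3-/-. Where the 3 probe sets lie relative to the disrupted part of the gene is not given in the sources used here, so they do not check the genotype, and the word knockout below stands for arrays labelled Smad3-/-. Genotype and strain background cannot be separated in this design.

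On the regular diet, some genes of heat-producing brown fat were far higher in the knockout than in wild type. Ucp1, the mitochondrial uncoupling protein of brown and beige fat, rose from 6.42 ± 0.03 to 12.38 ± 0.09 (SD, n = 2), a log2 difference of 5.96 ± 0.11 or 62.2-fold. Cidea, a lipid droplet protein abundant in brown fat, rose by 4.80 and Cox8b, a cytochrome oxidase subunit, by 3.92. Lep, which encodes the satiety hormone leptin, fell by 3.85 on the log2 scale, from 11.13 to 7.28. Genes of the epididymis had larger log2 differences than these. Lcn5 and Lcn8, lipocalins secreted there, were higher by 8.89 and 8.76, and Gpx5, a glutathione peroxidase of epididymal fluid, by 7.00.

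Of 30 measured brown and beige fat genes, 15 rose and 1 fell over all genes tested, and also when adjusted over the list alone (median 0.384, camera adjusted p = 8.1e-12). Fabp3, a fatty acid carrier, rose by 4.16. Ppargc1a, a coactivator of mitochondrial genes, and Prdm16, a brown fat regulator, did not pass, at 0.16 ± 0.15 and 0.26 ± 0.14. Fatty acid oxidation followed the same direction, with 16 of 28 genes higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 8.32e-10, adjusted p = 0.126 with an estimated correlation). Its receptor gene Ppara rose by 1.77, and the enzymes Acaa2 and Hadhb by 1.45 and 1.41. The white adipocyte list moved the other way, with 27 of 32 genes lower and 1 higher (29 and 1 adjusted over the list alone, camera adjusted p = 9.77e-25, adjusted p = 0.0502 with an estimated correlation). Beside Lep, its members Npr3, Rarres2 and Nnat fell, with log2 differences of -3.03, -2.68 and -2.49, and Adipoq and Slc2a4, the insulin-responsive glucose transporter, by 0.89 and 0.84. Fatty acid and triglyceride synthesis had 17 of 28 genes lower and 0 higher (19 and 1 adjusted over the list alone, camera adjusted p = 2.35e-09, adjusted p = 0.177 with an estimated correlation).

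Extracellular matrix genes were lower in the knockout on regular diet, 24 of 41 with 0 higher (27 and 1 adjusted over the list alone, camera adjusted p = 1.07e-14). Fn1 (fibronectin), Col4a1 (a basement membrane collagen) and Nid1 fell by 2.02, 2.00 and 1.94. Fibroblast and adipocyte precursor genes were lower too, 10 of 23 with 2 higher (13 and 4 adjusted over the list alone, camera adjusted p = 0.000159). Among 26 TGF-beta responsive genes, 14 were lower and 2 higher (16 and 3 adjusted over the list alone, camera adjusted p = 3.53e-08). The largest falls there were of Cnn1 and Tagln, contractile proteins of smooth muscle, by 4.54 and 3.28, and of Thbs1 (thrombospondin 1) by 3.15, while Ccn2 fell by 1.47. Cnn1 and Tagln are also in the smooth muscle and pericyte list, where 12 of 16 genes were lower and 0 higher (13 and 0 adjusted over the list alone, median -2.17, camera adjusted p = 6.96e-18). The WT_RD arrays also serve in the diet comparison in wild type, where this list fell too. On the high fat diet 8 of its genes were higher in the knockout and 1 lower. Macrophage genes were lower, 20 of 37 against 1 higher (20 and 2 adjusted over the list alone, camera adjusted p = 4.02e-09), with falls of 1.93 for Lyve1, 1.83 for Lgals3, 1.82 for Retnla and 1.65 for Lyz2. Adgre1, a macrophage surface marker, did not pass (-0.23 ± 0.11). Unfolded protein response genes were higher, 15 of 26 against 6 lower both over all genes and adjusted over the list alone (camera adjusted p = 6.57e-05, adjusted p = 0.126 with an estimated correlation).

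Markers of other tissues, and the 3' to 5' difference of Gapdh and actin, moved with these groups. The epididymis and testis list rose in 22 of 25 genes with 0 lower, also adjusted over the list alone (median 2.44, camera adjusted p = 1.29e-36). How much of the fat-cell, matrix, macrophage and unfolded protein response changes came with these genes was not tested. On the high fat diet, where they were not higher in the knockout, the white adipocyte median was 0.03. Macrophage genes were lower there too, 17 of 37 with 0 higher. The genes immediate early after stress and of heat shock, which respond to tissue handling, fell in 18 of 28 with 1 higher (18 and 2 adjusted over the list alone, camera adjusted p = 4.02e-09), among them Egr1 by 1.81 and Dusp1 by 1.77. Skeletal muscle genes went both ways, 18 higher and 5 lower of 39 (22 and 5 adjusted over the list alone, camera adjusted p = 0.00301, adjusted p = 0.149 with an estimated correlation), with Myh4, a fast myosin, higher by 2.55 and Tnnc2, a fast troponin, lower by 2.52. In all, 4361 of 18194 genes passed limma's test at an adjusted p under 0.05 for genotype on the regular diet, 1528 higher and 2833 lower in the knockout. Quantile normalization applied again made this split 2438 higher and 2572 lower. The genes named for this comparison that passed had SEs of 0.10 to 0.16 and adjusted p of at most 0.00579. At least 1.5-fold changes passed in 2128 genes. Of the 16 measured genes fixed by name in advance, 2 rose, 8 fell and 6 did not pass.

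**Figure D1:**
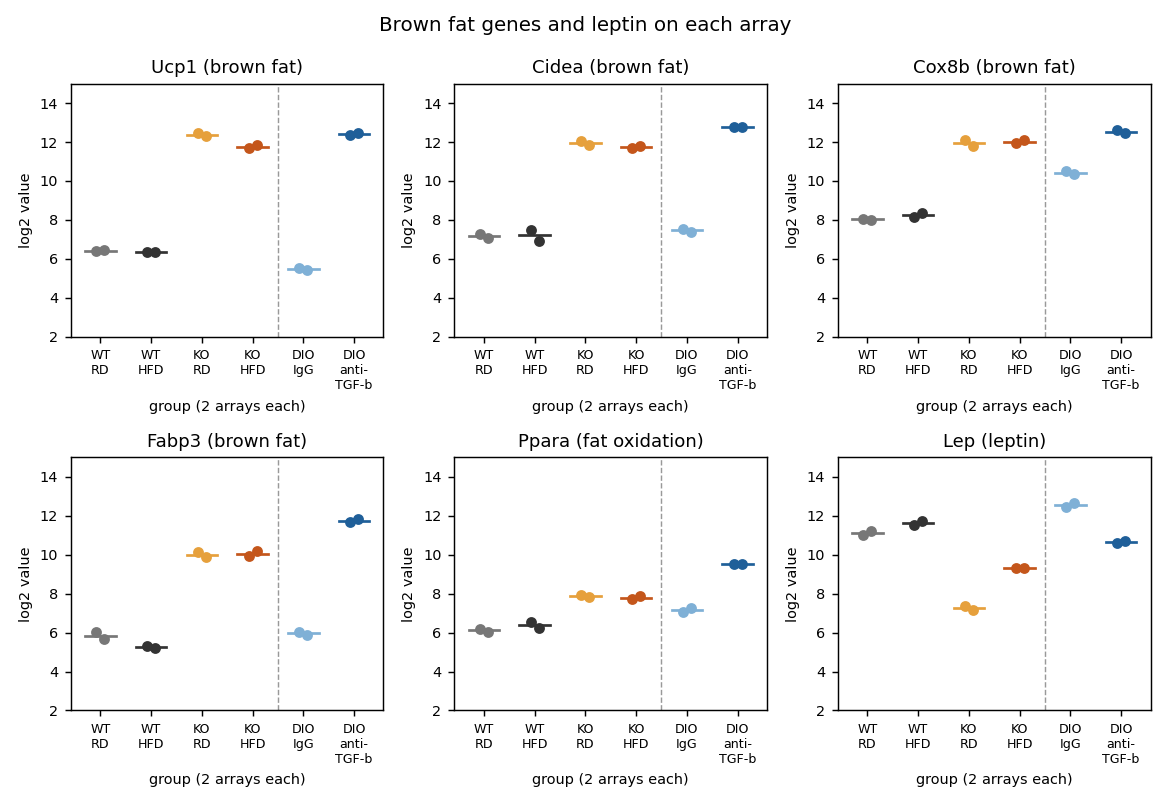
Deposited log2 value (vertical axis) of 6 genes on each of the 12 arrays, with a dot for each array and a line for each group's mean. Ucp1, Cidea, Cox8b, Fabp3 and Ppara are higher on both knockout groups than on wild type and higher with the TGF-beta antibody than with IgG, and Lep is lower (Ucp1 means of 6.42, 6.35, 12.38, 11.77, 5.48 and 12.40 from left to right). The dashed line separates the 2 experiments, whose levels are not comparable.

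On the high fat diet, the knockout again had higher brown fat genes, together with higher skeletal muscle and mitochondrial genes. Ucp1 averaged 11.77 ± 0.14 (SD, n = 2) against 6.35 ± 0.03 in wild type, a log2 difference of 5.41 ± 0.11 or 42.7-fold, and Cidea and Fabp3 were higher by 4.56 and 4.79. The fast muscle genes Tnnc2, Myh4 and Tnnt3 were higher by 6.57, 6.36 and 6.12. Lep was lower by 2.34 ± 0.11, falling from 11.64 to 9.30, and Mest, which marks fat-cell enlargement, averaged 8.28 against 10.94.

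Skeletal muscle genes rose in 38 of 39 with 0 lower, also adjusted over the list alone (median 3.19, camera adjusted p = 5.63e-134). Beside the 3 above they included Tnni2, Ckm and Atp2a1, higher by 5.64, 5.62 and 5.15. Of 18 regulators of muscle formation 2 rose and 1 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0883), with Myf6 higher by 1.13 and Myod1 at 0.26 ± 0.13. Oxidative phosphorylation rose in 65 of 77 genes with 0 lower (72 and 0 adjusted over the list alone, camera adjusted p = 4.73e-60, adjusted p = 0.0661 with an estimated correlation), including Sdhb by 1.65, Ndufv1 by 1.46 and Cyc1 by 1.36. Tricarboxylic acid cycle genes rose in 22 of 24 with 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 2.41e-43), Idh3b by 1.62 and Pdhb by 1.53. In fatty acid oxidation 23 of 28 were higher and 0 lower (25 and 1 adjusted over the list alone, camera adjusted p = 8.18e-41), with Acadvl and Pdk4 up by 1.99 and 1.97. The brown and beige fat list had 16 of 30 higher and 0 lower, also adjusted over the list alone (median 0.545, camera adjusted p = 2.19e-24). Regulators of mitochondrial formation had 6 of 24 higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 3.41e-05), Ppara by 1.41 and Ppargc1b by 1.40. Ppargc1a rose by 0.48 ± 0.15 (limma adjusted p = 0.039), and leaving out WT_HFD replicate a, KO_HFD replicate a or KO_HFD replicate b ended that call (adjusted p = 0.564, 0.214 and 0.137). Skeletal muscle expresses genes of these mitochondrial lists strongly, and its own markers rose beside them.

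Macrophage genes were lower in the knockout on high fat diet, 17 of 37 with 0 higher (18 and 0 adjusted over the list alone, camera adjusted p = 3.5e-13). Lgals3 (galectin 3) fell by 2.21, Gpnmb by 1.75, Cd68 by 1.57 and the lysosomal protease Ctss by 1.51, while Adgre1 stayed at -0.03 ± 0.11. Interferon response genes had 10 of 34 lower and 3 higher (11 and 4 adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.175 with an estimated correlation and 0.0573 without KO_HFD replicate b). Fatty acid and triglyceride synthesis was higher here, 15 of 28 with 3 lower (16 and 3 adjusted over the list alone, camera adjusted p = 3.26e-08, adjusted p = 0.248 with an estimated correlation), led by Tkt, Acacb and Elovl6 at 1.67, 1.14 and 1.11, and Fasn rose by 0.61. White adipocyte genes split, 9 higher and 8 lower of 32 (11 and 8 adjusted over the list alone, camera adjusted p = 0.983), their median at 0.03 and mean at -0.12. Slc2a4 was higher by 0.85 and Nnat and Npr3 lower by 1.77 and 1.40. Extracellular matrix genes did not pass as a list, with 8 of 41 lower and 0 higher (10 and 3 adjusted over the list alone, camera adjusted p = 0.104), Thbs1 lower by 1.24 and Lox, a collagen cross-linking enzyme, by 0.82. TGF-beta responsive genes did not pass either, with 4 higher and 4 lower of 26 (5 and 5 adjusted over the list alone, median -0.04, camera adjusted p = 0.866). Unfolded protein response genes, many of them higher in the knockout on regular diet, were lower here in 10 of 26 and higher in 1 (14 and 1 adjusted over the list alone, median -0.28, camera adjusted p = 3.79e-06, adjusted p = 0.0996 with an estimated correlation). Epididymis and testis genes were lower in 12 of 25 with 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 4.67e-12), among them Lcn5 by 3.72 and Prm1, a sperm protamine, by 2.52. Mammary and other epithelium genes were lower in 11 of 26 with 0 higher, also adjusted over the list alone (camera adjusted p = 8.21e-08). Smooth muscle and pericyte genes rose in 8 of 16 and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 5.76e-08), and circadian clock genes, which follow the hour of sampling, rose in 5 of 19 with 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.00047). For genotype on the high fat diet 1963 genes passed, 863 higher and 1100 lower. This split turned to 816 and 648 without WT_HFD replicate b and to 669 and 649 without KO_HFD replicate a, and was 558 and 984 without WT_HFD replicate a and 543 and 879 without KO_HFD replicate b. The named ones that passed had SEs of 0.10 to 0.24 and adjusted p of at most 0.039. At least 1.5-fold changes passed in 895 genes. Among the 16 measured genes fixed by name in advance, 8 rose, 1 fell and 7 did not pass.

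In obese mice, brown fat and skeletal muscle genes were higher and macrophage genes lower with the TGF-beta antibody. Ucp1 averaged 12.40 ± 0.08 (SD, n = 2) with the antibody and 5.48 ± 0.08 with IgG, a log2 difference of 6.93 ± 0.11 or 122-fold, and Fabp3 and Cidea rose by 5.79 and 5.29. Myh4 and Ttn, which encodes the giant muscle protein titin, rose by 7.03 and 6.84. Atp6v0d2, a proton pump subunit of macrophages, fell by 3.64, and Lep fell by 1.89 ± 0.11, from 12.55 to 10.67. Tph2, a serotonin-synthesis enzyme of neurons, averaged 8.88 with IgG and 3.63 with the antibody.

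Of the brown and beige fat list 21 of 30 genes rose and 2 fell, also adjusted over the list alone (median 1.01, camera adjusted p = 1.24e-17). Slc27a2, Ppara and Ppargc1a rose by 3.52, 2.36 and 1.67, whereas Prdm16 did not pass (-0.19 ± 0.14). Regulators of mitochondrial formation rose in 12 of 24 with 0 lower (13 and 1 adjusted over the list alone, camera adjusted p = 2.13e-06), with Ppargc1b higher by 1.48 and Sirt3 by 1.03. Oxidative phosphorylation rose in 56 of 77 with 0 lower (65 and 0 adjusted over the list alone, camera adjusted p = 2.12e-21, adjusted p = 0.25 with an estimated correlation), Ndufv1 by 1.07 and Cyc1 by 0.94. Fatty acid oxidation had 23 of 28 higher and 3 lower (24 and 3 adjusted over the list alone, camera adjusted p = 2.98e-12, adjusted p = 0.0981 with an estimated correlation), Acadvl by 1.42 and Acaa2 by 1.30. The 3' to 5' difference of actin was larger on both antibody arrays, at 0.87 and 0.75 log2 against 0.61 and 0.67 with IgG, and that of Gapdh was 0.085 and 0.14 against 0.02 and 0.10. Beside these lists, skeletal muscle genes rose in 38 of 39 with 0 lower, also adjusted over the list alone (median 4.58, camera adjusted p = 1.7e-94). Myogenic regulators did not pass as a list, with 5 higher and 2 lower of 18, also adjusted over the list alone (camera adjusted p = 0.178), though Myf6 and Myod1, transcription factors of muscle cells, rose by 1.65 and 1.04.

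Macrophage genes fell in 32 of 37 with 1 higher (33 and 1 adjusted over the list alone, median -1.10, camera adjusted p = 8.24e-31). The protease Mmp12 fell by 2.96, the integrin gene Itgax fell by 2.89, Gpnmb by 2.45 and Adgre1 by 1.87. Inflammatory mediators fell in 15 of 40 with 3 higher (16 and 3 adjusted over the list alone, camera adjusted p = 0.000309), Saa3 (serum amyloid A3) by 3.19, Ccl8 by 2.16 and Ccl2 by 0.72, while Tnf was at -0.28 ± 0.15. Cell cycle genes fell in 25 of 37 with 1 higher (29 and 1 adjusted over the list alone, camera adjusted p = 9.91e-16), with Birc5 at -2.63, Mki67 at -2.48, Ccnb2 at -2.44 and Top2a at -2.12. Cholesterol synthesis fell in 16 of 18 with 1 higher, also adjusted over the list alone (camera adjusted p = 5.48e-14), Lss by 1.82 and Fdps by 1.61. Hepatocyte genes, typical of liver, fell in 18 of 23 with 1 higher (19 and 1 adjusted over the list alone, median -1.46, camera adjusted p = 1.14e-21). Among them Fabp1 was at -3.54, Apoa2 at -3.36 and Alb (albumin) at -3.20. Whether other tissue on the IgG arrays added to the macrophage, inflammatory, cell cycle, cholesterol synthesis or matrix falls was not tested.

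Extracellular matrix genes were lower with the antibody, 25 of 41 with 7 higher (27 and 8 adjusted over the list alone, camera adjusted p = 3.65e-09, adjusted p = 0.0825 with an estimated correlation). The collagen genes Col3a1, Col5a2 and Col1a1 fell by 1.48, 1.48 and 1.13. Of the TGF-beta responsive genes 12 of 26 were lower and 4 higher (15 and 5 adjusted over the list alone, camera adjusted p = 0.00238, adjusted p = 0.203 with an estimated correlation), with Timp1 lower by 1.25 and Ccn2 at -0.29 ± 0.11. Tgfb1, the gene of the ligand, fell by 0.83. Mesothelial genes, from the lining of body cavities, rose in 13 of 19 with 1 lower (13 and 2 adjusted over the list alone, camera adjusted p = 5.15e-05), Bnc1 by 1.29 and Upk3b by 0.81. B and plasma cell genes rose in 11 of 20 with 4 lower (12 and 4 adjusted over the list alone, camera adjusted p = 0.00238, adjusted p = 0.0613 with an estimated correlation), Ms4a1 by 2.07. Circadian clock genes rose in 13 of 19 with 1 lower (14 and 3 adjusted over the list alone, camera adjusted p = 9.41e-08), Dbp by 1.57 and Usp2 by 1.26. White adipocyte genes split 9 and 9 of 32 (10 and 9 adjusted over the list alone, camera adjusted p = 0.892), with a median of 0.09 and a mean of -0.05. Unfolded protein response genes did not pass, with 9 of 26 lower and 3 higher (10 and 4 adjusted over the list alone, camera adjusted p = 0.0701). Epididymis and testis genes did not pass as a list, with 1 higher and 1 lower of 25 (0 and 0 adjusted over the list alone, camera adjusted p = 0.618). Altogether 4423 genes passed, 2135 higher and 2288 lower, and the named ones that passed had SEs of 0.10 to 0.18 and adjusted p of at most 0.0121. At least 1.5-fold changes passed in 1967 genes. From the 16 measured genes fixed by name in advance, 8 rose, 4 fell and 4 did not pass. Adipoq was higher by 0.35 (limma adjusted p = 0.0121), a call that ended without any 1 of the 4 antibody arrays (adjusted p from 0.0603 to 0.118).

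**Figure D2:**
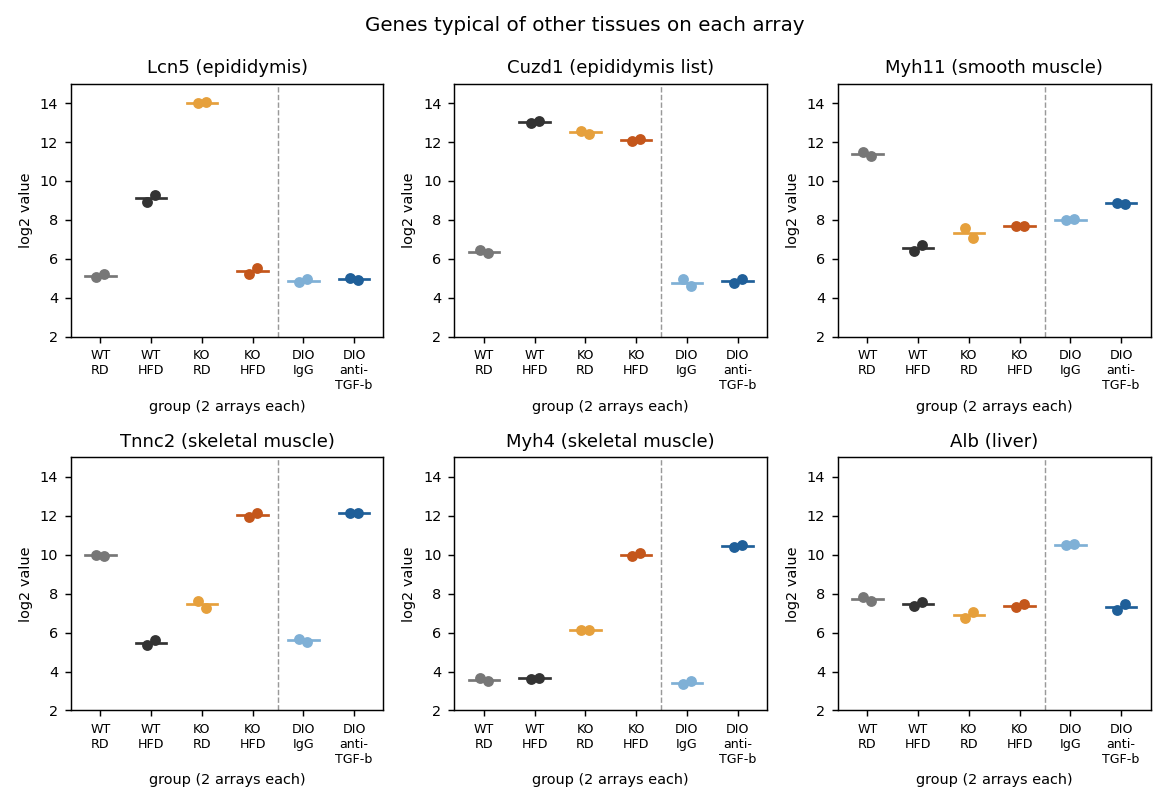
Deposited log2 value (vertical axis) of 6 genes typical of tissues other than fat on each of the 12 arrays, with a dot for each array and a line for each group's mean. Lcn5 (epididymis) is highest on the knockout arrays of the regular diet at 14.02, Cuzd1 is low only in wild type on regular diet among the 8 arrays of the first experiment (6.38), Myh11 (smooth muscle) is highest there (11.38), Tnnc2 and Myh4 (skeletal muscle) are high with the knockout on high fat diet and with the TGF-beta antibody, Tnnc2 is also high in wild type on regular diet (9.97, against 5.47 on high fat diet), and Alb (liver) is high with IgG (10.51). The dashed line separates the 2 experiments.

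In wild type, genes of smooth muscle were lower and genes of the epididymis higher on the high fat diet. Many genes of fat synthesis and of the tricarboxylic acid cycle were lower too, though as lists these calls ended with an estimated correlation (adjusted p = 0.196 and 0.0907). Tkt and Elovl6, an enzyme of the pentose phosphate path and a fatty acid elongase, fell by 1.92 each (SE 0.11), and Acly and Acaca, which make the building blocks of fatty acids, by 1.56 and 1.51. Lep rose by 0.51 ± 0.11, from 11.13 ± 0.04 to 11.64 ± 0.08 (SD, n = 2), and leaving out WT_RD replicate a or WT_HFD replicate b ended that call (adjusted p = 0.0958 and 0.0563). Slc2a4 and Fasn fell by 1.04 and 0.89. Actg2, Cnn1 and Myh11, contractile genes of smooth muscle, fell, with log2 differences of -5.96, -5.39 and -4.83, and Cuzd1 and Adam7, both expressed in the epididymis, rose by 6.65 and 5.02.

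Fatty acid and triglyceride synthesis fell in 14 of 28 genes and rose in 4 (15 and 4 adjusted over the list alone, camera adjusted p = 3.13e-10, adjusted p = 0.196 with an estimated correlation). Tricarboxylic acid cycle genes fell in 18 of 24 with 0 higher (20 and 1 adjusted over the list alone, camera adjusted p = 6.28e-16, adjusted p = 0.0907 with an estimated correlation), Pcx and Pdhb by 1.00 each. Oxidative phosphorylation fell in 31 of 77 and rose in 2 (39 and 3 adjusted over the list alone, camera adjusted p = 3.04e-13, adjusted p = 0.388 with an estimated correlation). Insulin signalling and glucose transport fell in 8 of 23 and rose in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 9.17e-05, adjusted p = 0.16 with an estimated correlation), Pik3r1 by 1.10. The brown and beige fat list did not pass, with 5 of 30 lower and 2 higher (6 and 2 adjusted over the list alone, camera adjusted p = 0.285), and Ucp1 was at -0.07 ± 0.11. Macrophage genes did not pass as a list either, with 5 higher and 4 lower of 37 (6 and 6 adjusted over the list alone, camera adjusted p = 0.572), among them Gpnmb and Lgals3 higher by 1.72 and 1.22 and Lyve1 lower by 1.31. Interferon response genes rose in 6 of 34 and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.000233, adjusted p = 0.0791 with an estimated correlation), Ifit3 by 1.45 and Irf7 by 0.90. Unfolded protein response genes rose in 9 of 26 and fell in 3, also adjusted over the list alone (camera adjusted p = 0.00156, adjusted p = 0.241 with an estimated correlation).

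Smooth muscle and pericyte genes fell in 12 of 16 with 0 higher (13 and 1 adjusted over the list alone, median -2.24, camera adjusted p = 1.59e-34). Beside them, TGF-beta responsive genes fell in 11 of 26 and rose in 3 (11 and 4 adjusted over the list alone, camera adjusted p = 3.09e-08, adjusted p = 0.0611 with an estimated correlation), with Cnn1 and Tagln (-3.66) among those that fell. Extracellular matrix genes fell in 16 of 41 and rose in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 7.75e-10, adjusted p = 0.0855 with an estimated correlation), Thbs1 by 1.33 and Col4a1 by 1.08. Epididymis and testis genes rose in 12 of 25 with 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 7.62e-19), Lcn5 by 3.97 and Prm1 by 3.01. Skeletal muscle genes did not pass as a list, with 3 higher and 7 lower of 39, also adjusted over the list alone (camera adjusted p = 0.143), their median at 0.03 and mean at -0.23, but Tnnc2 fell by 4.50 ± 0.12, from 9.97 to 5.47. Immediate early and heat shock genes fell in 16 of 28 with 0 higher, also adjusted over the list alone (camera adjusted p = 5.09e-16), Egr1 by 1.85 and Dusp1 by 1.81. The 3' to 5' difference of Gapdh and actin was larger on these high fat arrays than on WT_RD. Between diets 1966 genes differed in wild type, 854 higher and 1112 lower, and the named ones that passed had SEs of 0.10 to 0.19 and adjusted p of at most 0.00226. At least 1.5-fold changes passed in 945 genes. Within the 16 measured genes fixed by name in advance, 1 rose, 5 fell and 10 did not pass. Without WT_RD replicate a the count was 1296 (576 higher and 720 lower), and without WT_HFD replicate a the split turned to 713 higher and 691 lower.

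In the knockout, skeletal muscle genes were higher and epididymal genes lower on the high fat diet. Many white adipocyte and matrix genes were higher too, though as lists these calls ended with an estimated correlation (adjusted p = 0.0791 and 0.2). Lep rose from 7.28 to 9.30, by 2.02 ± 0.11, Rarres2, which encodes the adipokine chemerin, by 2.27, and Cidec, a lipid droplet protein, by 1.73. Ucp1 fell by 0.61 ± 0.11, from 12.38 to 11.77, and Cidea did not pass (-0.21 ± 0.13). Myh7, Myl2 and Tnnt3, sarcomere genes, rose by 4.98, 4.81 and 4.78, while Lcn8, Lcn5 and Gpx5 fell by 8.74, 8.65 and 6.88.

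White adipocyte genes rose in 26 of 32 with 0 lower (27 and 0 adjusted over the list alone, camera adjusted p = 2.4e-29, adjusted p = 0.0791 with an estimated correlation), Adipoq by 0.85 and Retn (resistin) by 1.17 among them. Lipolysis and lipid droplet genes rose in 12 of 17 with 0 lower (12 and 1 adjusted over the list alone, camera adjusted p = 6.62e-12, adjusted p = 0.0791 with an estimated correlation), Abhd5 by 1.44 and Plin4 by 1.24. Fatty acid and triglyceride synthesis rose in 17 of 28 and fell in 3 (19 and 5 adjusted over the list alone, camera adjusted p = 7.25e-07, adjusted p = 0.32 with an estimated correlation), Insig1 by 2.16 and Agpat2 by 1.20. Oxidative phosphorylation rose in 42 of 77 and fell in 1 (59 and 3 adjusted over the list alone, camera adjusted p = 1.26e-13, adjusted p = 0.347 with an estimated correlation). Extracellular matrix genes rose in 22 of 41 and fell in 1, also adjusted over the list alone (camera adjusted p = 4.7e-07, adjusted p = 0.2 with an estimated correlation), Fn1 by 1.21 and Col3a1 by 0.93. TGF-beta responsive genes rose in 9 of 26 and fell in 2 (10 and 4 adjusted over the list alone, camera adjusted p = 0.0429, adjusted p = 0.347 with an estimated correlation), a list call that also ended without KO_RD replicate b or KO_HFD replicate b (adjusted p = 0.0573 and 0.0988) and without dim probe sets (0.111). Macrophage genes rose in 12 of 37 and fell in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00498, adjusted p = 0.286 with an estimated correlation). Endothelial genes rose in 13 of 21 and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 8.66e-07, adjusted p = 0.2 with an estimated correlation), Vwf by 1.16. Unfolded protein response genes fell in 13 of 26 and rose in 1 (15 and 2 adjusted over the list alone, camera adjusted p = 8.88e-09, adjusted p = 0.0791 with an estimated correlation), Manf by 1.88 and the chaperone Hspa5 by 1.29.

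Skeletal muscle genes rose beside these in 37 of 39 with 0 lower (38 and 0 adjusted over the list alone, median 2.85, camera adjusted p = 3.02e-82), and epididymis and testis genes fell in 18 of 25 with 0 higher, also adjusted over the list alone (median -1.29, camera adjusted p = 1.93e-35). The white adipocyte median was 0.95 here and -0.09 for diet in wild type. How much of the white adipocyte and matrix rises came with the epididymal fall was not tested. The brown and beige fat list had 6 of 30 lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.00922, adjusted p = 0.222 with an estimated correlation and 0.0546 without KO_RD replicate a), Cited1 by 1.32. Between diets 3150 genes differed in the knockout, 2091 higher and 1059 lower, and the named ones that passed had SEs of 0.10 to 0.15 and adjusted p of at most 0.0398. At least 1.5-fold changes passed in 1413 genes. Of all the 16 measured genes fixed by name in advance, 6 rose, 1 fell and 9 did not pass. Without KO_HFD replicate b the count was 2035 (1274 higher and 761 lower).

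**Figure D3:**
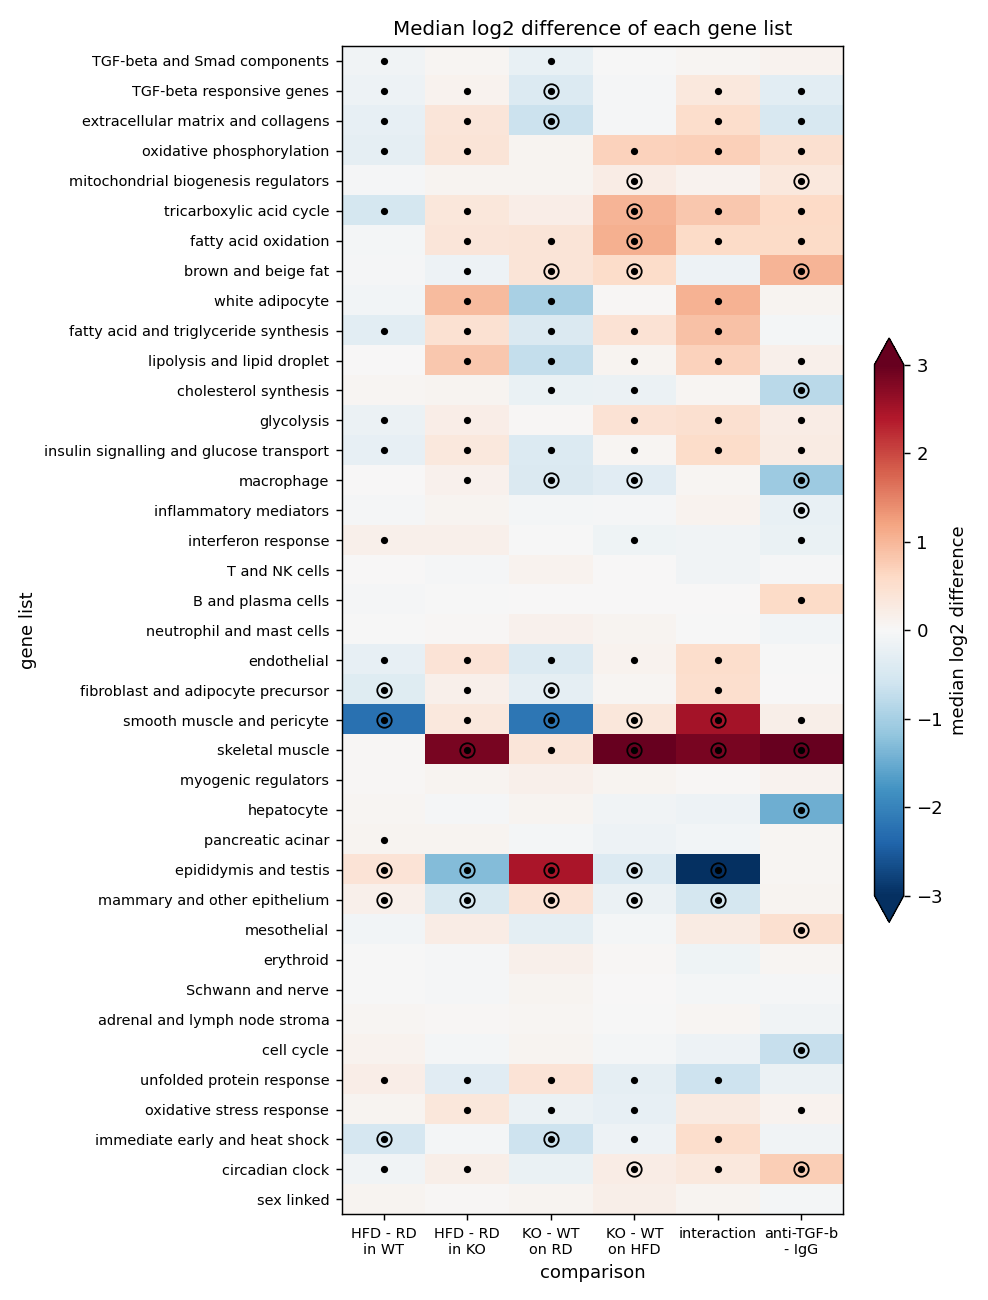
Median log2 difference of the measured members of each of the 39 gene lists in 6 comparisons, as colour from blue (lower) to red (higher), with the scale given by the bar. A dot marks a list that passed camera at an adjusted p under 0.05, and a ring around it one that also passed with an estimated correlation. Skeletal muscle genes are high in the knockout on high fat diet (3.19) and with the antibody (4.58), and macrophage genes are low in both genotype comparisons and with the antibody (-0.44, -0.33 and -1.10).

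The response to the diet differed between genotypes in 3413 genes by limma's interaction test, 2181 with a more positive and 1232 with a more negative diet effect in the knockout. Genes expressed in fat cells were among the first. The diet effect on Slc2a4 was -1.04 in wild type and 0.64 in the knockout, an interaction of 1.68 ± 0.15. That on Retn was -0.65 and 1.17 (interaction 1.82 ± 0.17). Skeletal muscle genes had a median interaction of 2.85 on the same arrays, and how much of the Slc2a4 value came with them was not tested. The white adipocyte median was -0.98 for genotype on regular diet and 0.03 on high fat diet. How much of the fat-cell interactions came with the epididymal genes of the KO_RD arrays was not tested either. Pparg, the master regulator of fat cells, Me1, Pcx and Cidec had interactions of 1.99, 2.02, 1.86 and 1.83, and Lep one of 1.51. Ucp1 had -0.54 ± 0.15, and Cidea did not pass (-0.24 ± 0.18). Leaving out KO_HFD replicate a ended the call for Ucp1 (adjusted p = 0.0745). Of the 16 genes fixed by name in advance, 7 had a positive interaction, 1 a negative one and 8 did not pass.

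White adipocyte genes had a positive interaction in 26 of 32 and a negative one in 2, also adjusted over the list alone (camera adjusted p = 1.01e-20, adjusted p = 0.0761 with an estimated correlation). In fatty acid and triglyceride synthesis the counts were 21 and 1 of 28 (23 and 1 adjusted over the list alone, camera adjusted p = 1.07e-15, adjusted p = 0.0931 with an estimated correlation), and in the tricarboxylic acid cycle 19 and 0 of 24 (23 and 0 adjusted over the list alone, camera adjusted p = 2.62e-15, adjusted p = 0.0856 with an estimated correlation). Brown and beige fat genes did not pass, with 4 and 4 of 30, also adjusted over the list alone (camera adjusted p = 0.562). Lists of other tissues gave the largest medians, with 37 of 39 skeletal muscle and 12 of 16 smooth muscle genes positive and 0 negative (37 and 13 adjusted over the list alone, medians 2.85 and 2.50, camera adjusted p = 8.88e-59 and 4.56e-22). Epididymis and testis genes were negative in 23 of 25 (24 adjusted over the list alone, median -3.28, camera adjusted p = 7.66e-47), with Lcn5 at -12.6 ± 0.20, where wild type rose and the knockout fell with the diet. Mammary and other epithelium genes were negative in 12 of 26 and positive in 0 (13 and 0 adjusted over the list alone, camera adjusted p = 1.34e-11). TGF-beta responsive genes were positive in 11 of 26 and negative in 2 (13 and 2 adjusted over the list alone, camera adjusted p = 1.56e-06, adjusted p = 0.0761 with an estimated correlation), and unfolded protein response genes negative in 13 of 26 and positive in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 9.15e-08, adjusted p = 0.0761 with an estimated correlation).

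Averaged over diets, 3534 genes differed by genotype, 1156 higher and 2378 lower in the knockout, and quantile normalization applied again gave 1805 higher and 2200 lower. Among genes whose arrays did not overlap between the sides, Ucp1, Cidea, Fabp3, Myh4 and Cox7a1 were higher by 5.69, 4.68, 4.48, 4.45 and 4.15, and Lep, Hpgd (a prostaglandin-degrading enzyme) and Synpo2 were at -3.09, -2.65 and -2.52. Fatty acid oxidation rose in 23 of 28 genes with 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 5.2e-29), brown and beige fat in 17 of 30 with 1 lower, also adjusted over the list alone (1.74e-20), and macrophage genes fell in 24 of 37 with 0 higher, also adjusted over the list alone (2.1e-16). Beside them skeletal muscle rose in 38 of 39 with 0 lower (39 and 0 adjusted over the list alone, 1.66e-71) and epididymis and testis in 19 of 25 with 3 lower (19 and 4 adjusted over the list alone, 1.68e-20), while smooth muscle and pericyte fell in 11 of 16 with 0 higher (12 and 1 adjusted over the list alone, 6.25e-11) and immediate early and heat shock in 18 of 28 with 1 higher (19 and 2 adjusted over the list alone, 3.16e-09). Some of these averages join opposite effects. Epididymis and testis genes were higher in 22 of 25 on the regular diet but lower in 12 on the high fat diet. Smooth muscle and pericyte genes were lower in 12 of 16 on the regular diet, and 8 were higher and 1 lower on the high fat diet. Of the genes fixed by name, 5 rose, 6 fell and 5 did not pass. Of the 3534 genes, 1438 had arrays that did not overlap between the sides. As 2 groups of 4 arrays without diet in the model, the count of called genes was 266. Averaged over genotypes, 1922 genes changed with the diet, 1205 higher and 717 lower, and 11 as 2 groups of 4 without genotype in the model. Of the 1922 genes, 421 had arrays that did not overlap between the sides. Again among genes whose arrays did not overlap, Myom2, a muscle M-line protein, Tmed6 and Defb11 rose by 3.03, 2.31 and 2.28. Actg2, Plac8 and Cited1 were at -4.59, -3.46 and -2.77. Defb11 is a beta-defensin, a family expressed in the epididymis. Skeletal muscle genes rose in 35 of 39 with 0 lower (36 and 0 adjusted over the list alone, camera adjusted p = 2.51e-75), smooth muscle and pericyte genes fell in 11 of 16 with 1 higher, also adjusted over the list alone (1.02e-21), and immediate early and heat shock genes in 15 of 28 with 0 higher (16 and 1 adjusted over the list alone, 8.18e-13). The skeletal muscle rise came from the knockout, where 37 of 39 genes rose, against 3 higher and 7 lower in wild type. The smooth muscle fall came from wild type (12 of 16 lower), and in the knockout 6 rose and 2 fell. Of the genes fixed by name, 3 rose, 3 fell and 10 did not pass. Genes named here that passed had SEs of 0.07 to 0.12 for genotype and 0.07 to 0.13 for diet.

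The genotype effect on the high fat diet and the antibody effect, which share no array, resembled each other across genes. Their log2 differences correlated at Pearson r = 0.518 and Spearman rho = 0.272 over 18194 genes, against -0.161 to 0.169 for differences between arrays of the same group. Genes are not independent replicates. That range covers only the spread between arrays of a group, so it does not bound what tissue differences shared by both comparisons would give. Of the 39 skeletal muscle genes, 97.4% were called higher in both, and how much of the correlation came with them was not tested. Both comparisons had 559 genes higher and 422 lower, against 101 and 138 if the lists were independent, and 24 and 74 genes went opposite ways, against 109 and 129. Diet effects in wild type and knockout correlated at r = -0.223 (rho = -0.234), with 479 genes lower in wild type and higher in the knockout and 289 the reverse, against 128 and 49.7 if independent, and 129 higher and 78 lower in both, against 98.1 and 64.7. Genotype effects on the 2 diets went opposite ways in 340 and 258 genes, against 92.4 and 134 if independent, and the same way in 149 higher and 409 lower, against 72.5 and 171. They had r = -0.00913 (rho = 0.0275), and the diet effect in wild type and the antibody effect r = -0.111 (rho = -0.109), inside the range given by arrays of 1 group. Yet 335 genes were lower with the diet in wild type and higher with the antibody and 204 the reverse, against 130 and 107 if independent, and 117 were higher and 154 lower in both, against 100 and 140. The genotype effect on the regular diet and the antibody effect, at r = 0.0789 (rho = 0.0363), shared 309 higher and 604 lower genes, against 179 and 356, and went opposite ways in 194 higher and 436 lower in the knockout, against 192 and 332.

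**Figure D4:**
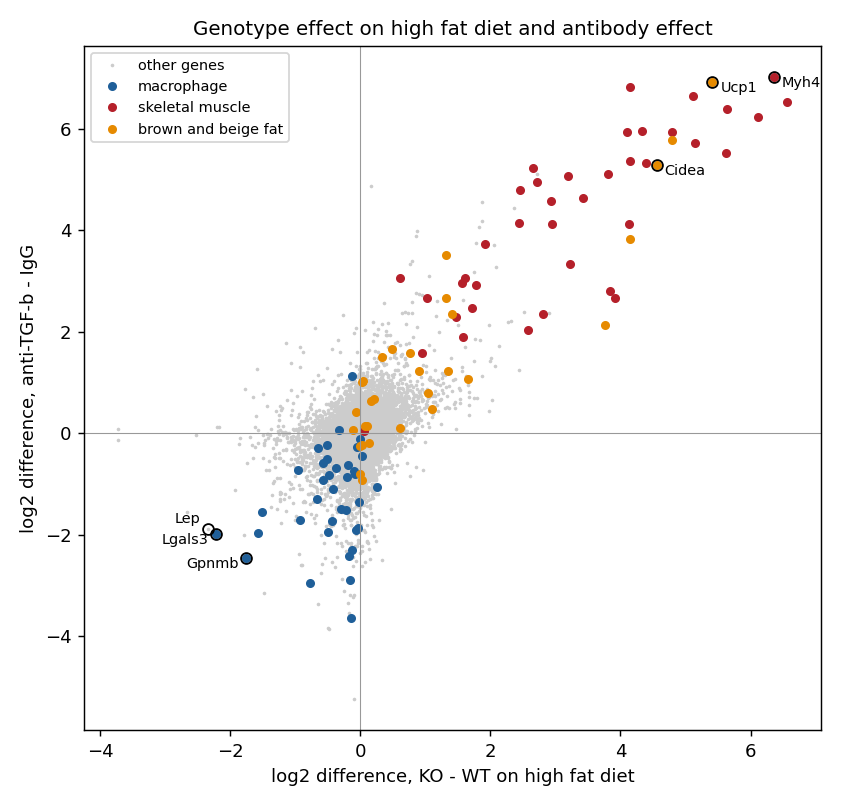
Log2 difference between knockout and wild type on the high fat diet (horizontal axis) and between TGF-beta antibody and IgG in obese mice (vertical axis), with a dot for each of the 18194 genes (Pearson r = 0.518). Skeletal muscle genes (red) lie mostly at the upper right, brown fat genes (orange) there or near the centre, and macrophage genes (blue) mostly below the horizontal line. Circles mark the genes labelled by name.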

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

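The tests of explanations for the epididymal and skeletal muscle genes were chosen after the result was seen.

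The diet effect differed between genotypes by the test of the difference itself in 3413 genes and, as whole lists, in 19 of 39. Lists with a more positive diet effect in the knockout had median interactions of 2.85 log2 for skeletal muscle, 2.5 for smooth muscle and pericyte, 1.04 for white adipocyte, 0.88 for fatty acid and triglyceride synthesis, 0.81 for the tricarboxylic acid cycle, 0.71 for oxidative phosphorylation and 0.7 for lipolysis and lipid droplet genes. Smaller ones were 0.57 for fatty acid oxidation, 0.55 for insulin signalling and glucose transport, 0.54 for endothelial, 0.53 for immediate early and heat shock, 0.52 for extracellular matrix, 0.49 for glycolysis, 0.49 for fibroblast and adipocyte precursor, 0.33 for circadian clock and 0.31 for TGF-beta responsive genes. More negative in the knockout were epididymis and testis at -3.28, unfolded protein response at -0.63 and mammary and other epithelium at -0.52. Quantile normalization applied again lowered some medians, to 0.38 for oxidative phosphorylation, 0.51 for the tricarboxylic acid cycle and 0.29 for immediate early and heat shock. It moved others further out, to 3.17 for skeletal muscle, -3.73 for epididymis and testis and -0.78 for the unfolded protein response. With an estimated correlation 4 of the 19 lists passed, which were those of skeletal muscle, smooth muscle and pericyte, epididymis and testis, and mammary and other epithelium, and the call of the other 15 ended, the fat-cell and metabolic lists among them.

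Probe sets that name no gene or several were left out of every comparison by gene. Apart from the array's control probe sets, these were 10092. Among them the diet changed 304 in wild type and 469 in the knockout, genotype 853 on the regular and 288 on the high fat diet, and the antibody 1268.

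Epididymis and testis genes were higher on the KO_RD than on the WT_RD arrays in 22 of the 25 listed. Loss of Smad3 by itself would have raised them on the high fat diet too, and the list's median there was -0.41, with 12 genes lower and 0 higher. The WT_HFD arrays on the other side carried these genes as well, 12 of 25 higher than on WT_RD and 0 lower. The value of -0.41 therefore does not settle what loss of Smad3 does, and the genes also rose without it. Of the listed genes, Cuzd1 was high on the KO_HFD arrays too, at 12.07 and 12.16 against 6.47 and 6.28 on WT_RD. Lcn5 was not, at 5.21 and 5.55 against 5.05 and 5.22. Epididymal tissue in the sample may account for the listed genes. Of all 48 measured genes outside the list in families expressed in the epididymis (beta-defensin, lipocalin, Pate, Wfdc, Cst and Rnase), 19 were called higher on KO_RD and 3 lower. That was 39.6% higher against 8.21% of 18121 other genes (Fisher's exact test, two-sided, p = 2.82e-09). The families were chosen after the list's rise was seen. Related genes are not independent, so this p measures no spread between samples. Carried-over tissue and an effect of genotype on such genes would both raise these families, so the test cannot tell them apart. Both KO_RD arrays carried the listed genes alike, with a median absolute difference of 0.133 at percentile 48 of 10000 matched lists (their median 0.136), but the WT_HFD and KO_HFD arrays differed by 0.283 and 0.198, at percentiles 100 and 99.3, so whether 1 RNA preparation or pool lay behind both arrays of a group stays open. The labels do not say how the tissue was taken, and an effect of Smad3 loss that the diet reverses was not tested.

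Skeletal muscle genes were high with the knockout on the high fat diet and with the TGF-beta antibody, 97.4% of the 39 in both comparisons. Loss of Smad3 by itself would have raised them about as much on the regular diet, where the median was 0.35 against 3.19. Muscle tissue in the sample may account for them, and so may a muscle program turned on in fat where TGF-beta signalling is blocked. In the knockout such a program would need the high fat diet as well, given the median of 0.35 without it. Tissue and program cannot be told apart, because either would bring the genes of mature muscle that the list holds. The brown fat and mitochondrial lists rose on the same arrays. On regular diet, 15 of 30 brown and beige fat genes rose in the knockout and 1 fell, with that muscle median of 0.35. With the diet in the knockout, 37 of 39 muscle genes rose, while 1 brown and beige fat gene rose and 6 fell. These values argue against muscle as the main source of the brown fat rise in the knockout. How much of the mitochondrial rise, or of any rise with the antibody, came with the muscle genes was not tested.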

How the results depend on the processing

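Fits without the KO_RD or the WT_RD group were chosen after seeing the data; the other alternatives were planned. Counts of called genes stayed within 1.5 times the reported ones under most alternatives. A minimum of 1.5-fold, which by its construction removes genes, left 945 (diet, wild type), 1413 (diet, knockout), 2128 and 895 (genotype on regular and high fat diet), 1967 (antibody), 851 (genotype averaged) and 477 (diet averaged). As 2 groups of 4 arrays, where the other factor adds to the spread, 266 and 11 genes were called for genotype and diet averaged. Leaving out 1 array, with fewer arrays in the fit, gave 1296 (without WT_RD a) to 1679 for diet in wild type and 2035 (without KO_HFD b) to 2710 in the knockout. Without the KO_RD group the counts were 2103 (diet, wild type), 2078 (genotype, high fat) and 4543 (antibody), and without the WT_RD group 3076 (diet, knockout), 1915 and 4306. The replicate letters do not pair the samples, as differences between b and a correlated between groups at -0.161 to 0.169. With the letter as a block the counts were 1959, 3128, 4358, 1947, 3408, 4412, 3534 and 1905 in the order of diet in wild type and knockout, genotype on each diet, interaction, antibody, and both averages. The correlation of genotype and antibody effects was 0.272 by Spearman's rho. Over all comparisons 159 list tests passed, 51 with an estimated correlation and 294 by fry in either direction, which asks another question. Of 1131 recomputed list values 1038 kept direction and side of the threshold, 54 no longer passed (48 with the estimated correlation), 28 newly passed and 11 reversed. The reversed ones had not passed. They were white adipocyte for genotype on high fat diet (adjusted p = 0.0982 by fry, 0.975 with the block, 0.575 without WT_HFD a and 0.68 without KO_HFD b, in a range without 1 array of 0.575 to 0.923), TGF-beta responsive genes there (0.708 by fry, 0.79 without WT_HFD a and 0.83 without KO_HFD b, in a range of 0.61 to 0.83), white adipocyte for the antibody (0.546 by fry, 0.944 without IgG a and 0.989 without antibody a, in a range of 0.913 to 0.989), and epididymis and testis for the antibody (0.908 without IgG a, in a range of 0.223 to 0.908). Of 5237 values of 356 gene results, 5173 kept both, 21 lost the call, 12 gained it and 31 reversed, none of them called in either setting. Smad3 was at -0.06 by another probe set (genotype averaged), 0 centred (diet, wild type) and -0.17 by the mean of probe sets (antibody). For diet in the knockout, Fasn centred was 0, Tgfb1 -0.03 and Myod1 -0.32 by the mean of probe sets, and Ccn2 -0.05 after quantile normalization, and for the antibody Prdm16 was 0.03 by the mean. Without 1 array, log2 differences ranged for diet in wild type from -0.02 to 0.05 (Smad3), -0.22 to 0.29 (Cidea), -0.3 to 0.2 (Ppargc1a), -0.17 to 0.11 (Prdm16) and -0.23 to 0.11 (Tnf). For diet in the knockout they ranged from -0.1 to 0.01 (Smad3), -0.01 to 0.18 (Tgfb1), -0.1 to 0.13 (Ccn2), -0.14 to 0.33 (Ccl2) and -0.09 to 0.17 (Myod1). Other ranges were -0.08 to 0.22 (Tnf, genotype on regular diet), -0.01 to 0.27 (Prdm16) and -0.08 to 0.02 (Adgre1, both genotype on high fat diet), -0.5 to 0.01 (Cidea, interaction), and for Smad3 -0.02 to 0.14 (antibody) and -0.04 to 0.01 (diet averaged). Apart from fewer arrays or genes, the cause was not tested. Signal over background was not measured here, and folds of dim probe sets may be compressed.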

Other observations

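The test of neighbouring genes and the counts of splits were planned before the result was seen, and the genes named in this part were chosen after their values were seen.

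The knockout on each diet and the antibody shared a group of genes that moved one way, although the genotype effects on the 2 diets also went opposite ways in many genes (340 higher on regular and lower on high fat diet, 258 the reverse, against 92.4 and 134 if independent, beside 149 higher and 409 lower on both). All 3 comparisons, which share no array, called 127 genes higher, against 8.49 if the calls were independent, and 226 lower, against 21.5. The calls came from 1 fit with a common spread per gene and are not independent. These expected counts are therefore no strict baseline for the size of the group. Beside Ucp1, Cidea and Fabp3, the higher group held Cox7a1, a cytochrome oxidase subunit (4.15 on regular diet, 4.15 on high fat diet, 3.83 with the antibody), Coq8a (1.83, 2.90 and 2.38), needed for coenzyme Q, Pank1 (2.40, 1.32 and 2.67), which starts coenzyme A synthesis, and Gpd2, the mitochondrial glycerol phosphate dehydrogenase (1.16, 2.52 and 2.40). Elovl3, a fatty acid elongase of brown fat, was at 1.10, 0.76 and 1.58. Skeletal muscle genes stood in the same group, among them Myh4 (2.55, 6.36 and 7.03), Atp2a1 (1.18, 5.15 and 5.73), Tnnt3 (0.89, 6.12 and 6.23) and Mb (0.72, 4.10 and 5.94). In the lower group were Lep, the lysosomal and macrophage genes Lgals3 (-1.83, -2.21 and -1.99), Cd68 (-1.34, -1.57 and -1.97) and Ctss (-1.15, -1.51 and -1.55), and the fat-cell genes Mest (-1.46, -2.67 and -1.56) and Sfrp5 (-0.76, -1.23 and -1.17). Zic1, a gene of classical brown fat, averaged 5.69, 5.30, 5.69 and 5.34 on WT_RD, WT_HFD, KO_RD and KO_HFD arrays, under the medians of those arrays.

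Epithelial genes moved with the epididymal ones. The mammary and other epithelium list rose with the diet in wild type in 10 of 26 genes with 2 lower, also adjusted over the list alone (camera adjusted p = 2.57e-06), fell in the knockout in 14 with 1 higher (16 and 1 adjusted over the list alone, 4.84e-12), and was higher in the knockout on regular diet in 13 with 1 lower (16 and 1 adjusted over the list alone, 3.53e-08). Fibroblast and adipocyte precursor genes fell with the diet in wild type in 10 of 23 with 0 higher (12 and 0 adjusted over the list alone, 4.28e-06). Endothelial genes were lower in the knockout on the regular diet in 12 of 21 with 0 higher (14 and 0 adjusted over the list alone, 3.19e-06, adjusted p = 0.126 with an estimated correlation). T and NK cell genes did not pass in the antibody comparison, where 8 of 28 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.167).

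Genotype and strain background differ together, and DNA of the strain in which the gene was targeted may remain beside Smad3 and alter its neighbours. Of the 100 measured genes nearest to Smad3 in gene order, 6 were called the same way by genotype on both diets, against 550 of 17931 others (6% and 3.07%, odds ratio 2.02, 95% interval 0.719 to 4.58, Fisher's exact test, two-sided, p = 0.132). The bound set in advance counted any p at or over the threshold against this explanation, which was wrong, since the interval reaches 4.58, and the question stays open. The 6 genes were Fem1b, Tle3, Cilp, Hexa, Ciao2a and Tln2. Strain differences elsewhere in the genome were not tested.

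As 2 groups of 4 arrays, the genotype split called 266 genes and the diet split 11. Of the 35 splits of the 8 arrays, the real one included, 2 called at least as many as the genotype split and 3 at least as many as the diet split, with 312 the highest other for both, so this test does not exclude chance. It says no more about chance than that, because the other splits counted were themselves factors of the design. One, at 312, set WT_RD and KO_HFD against WT_HFD and KO_RD, which is the interaction and points to a structure of the samples, and for diet the other was the genotype split. The splits that divided a group called 0 genes.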
